A study of Mus musculus with 26 samples.

How the data were processed

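RNA sequencing was carried out on 26 libraries of mouse embryonic stem cells, either wild type (WT) or carrying a knockout of Hmces (HMCES-KO). Per the labels, the cells were of the C57BL/6 strain and were grown in serum medium on gelatin, without a feeder layer being named. The WT columns of the untreated TPM table carry the name CCE, and whether it stands for another cell line or strain is not given in the sources used here. RNA was purified with a TIANGEN kit, and libraries were built with an Illumina TruSeq RNA kit. Cells were left untreated or were treated for 2 h with 50 ng/ml activin A, 10 µM SB431542, 10 ng/ml BMP4 or 50 nM LDN193189.

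The deposited tables were of 2 kinds. The count table held the authors' whole-number counts of read pairs per gene for 6 untreated libraries, made with featureCounts 2.0.1 in paired mode over exons summed by gene on the mm10 RefSeq gene annotation, per the file headers. The alignments counted there carried the name "highQuality", and the filter behind that name is not given in the sources used here, nor is a strand setting. FastQC 0.11.5, Bowtie2 2.3.3, SAMtools 1.9, featureCounts 2.0.1 and DESeq2 were named for the series per the submitters' processing notes, with mm10 as the genome build. The other 5 tables held TPM (reads divided by gene length and scaled to a sum of 1000000 within each library) computed by the authors, with 4 libraries in each. The deposited TPM table of untreated cells listed the same 25239 genes as the count table. The deposited TPM tables of treated cells listed 13438 genes for activin A, 13482 for SB431542, 13468 for BMP4 and 13492 for LDN193189, and the filter that set these lists is not given in the sources used here.

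TPM keeps no depth of its own, so the whole reads behind it were recovered. Of the values above 0 in the untreated table, 100% came out as whole reads within a tolerance of 0.01 reads, using the gene lengths of the count table. In the treated tables a unit was solved for each gene, which partly fixes the outcome, and 99.7% to 99.9% of the values above 0 came out whole, with 98.5% of the genes solvable. The gene lengths implied by the treated tables lay within 5% of those of the count table for 13.3% of the genes, so untreated and treated levels are not comparable. On simulated TPM of 2000 genes, with the scale of each library given, the search for the unit returned 100% of the genes exactly. The scale of each treated library had to be estimated from the data, and that estimate was not simulated. Total counts per library, in units of 1000000 reads, ran from 9.57 to 13.5 in the count table. The recovered totals ran from 8.52 to 10.0 in the untreated TPM table and from 4.12 to 5.55 in the treated tables.

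Groups were taken from the sample labels. The count table names its knockout lines KO7 and KO8, the labels name them HMCES-KO1 and HMCES-KO2, and which is which is not given in the sources used here, so KO7 and KO8 are used for that table. The mean of both lines does not depend on this. The line behind the HMCES-KO libraries of the untreated TPM table is not given in the sources used here either. In each treated table the HMCES-KO libraries came from the lines labelled KO1 and KO2, with 1 library of each, so the spread within a treated HMCES-KO group includes the difference between lines. The mean of the treated tables takes libraries of the same line in different tables as separate, so its p-values do not measure the spread between knockout lines. Nothing in the labels says that libraries of one group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

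The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. Counts were tested with edgeR 4.0.16 (TMM scaling, its expression filter by group, quasi-likelihood test) in 3 groups of 2 libraries. TPM was tested with limma 3.58.1 with a trended prior on log2(TPM + 1), keeping genes with a TPM of at least 1 in at least 2 libraries of the fit. Fold changes of TPM are therefore on the log2(TPM + 1) scale, which understates the change of genes with low values. The 16 treated libraries were fitted together as 8 groups of 2, on the 12928 genes present in all 4 tables, after rescaling each library to 1000000 over those genes, which held 99.9% to 100% of its TPM. Treatment and table are the same split in every contrast between treatments. The 4 untreated TPM libraries were fitted alone. Adjustment was by Benjamini-Hochberg within a contrast, and a gene was called at an adjusted p under 0.05. All fold changes are HMCES-KO minus WT, or ligand minus inhibitor, on the log2 scale, and are given with their standard error.

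A set of 20 gene lists covered Nodal/activin SMAD2/3 targets, BMP SMAD1/5 targets, TGF-beta family ligands, receptors and SMADs, naive pluripotency, general pluripotency, formative and primed pluripotency, primitive streak and mesoderm, endoderm, neuroectoderm, trophectoderm, the 2-cell-like state, germline genes, p53 targets, base excision repair and DNA demethylation, Wnt targets, immediate early genes, the integrated stress response, hypoxia and glycolysis, fibroblast markers (feeder cells), and mitochondrial transcripts as a sign of RNA quality. The lists share some genes, such as Smad7 and Bambi between the first pair. Lists with at least 3 measured members were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within a contrast. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, the calls that held were the Nodal/activin list in the ligand contrast of HMCES-KO and in the activin interaction, and the BMP and Nodal/activin lists in the BMP4 against LDN193189 contrast of HMCES-KO.

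Genes were named by a fixed rule. Hmces came first in every library. Next came, among called genes with an ordinary symbol, a mean logCPM of at least 1 or a mean TPM of at least 2, and no overlap between the libraries of both sides, the 10 with the largest rise and the 10 with the largest fall for the mean contrasts and 5 of each for single tables and ligand contrasts. Up to 4 members with the smallest p were added from each list described, and any member of the Nodal/activin and BMP lists. Not every gene that met the rule is printed. Genes named outside this rule are stated to have been chosen after their values were seen.

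Replicate pairs were compared before averaging. Over the 13 pairs the chi-square per degree of freedom of the reads ran from 1.52 to 11.3, so no pair differed by as little as sampling noise and none was counted as 1 library. Replicate numbers of the treated HMCES-KO libraries mark the same named lines across tables, and the deviations of same-numbered libraries correlated at 0.227 to 0.323 across genes in 6 pairs of groups. In the treated WT groups these correlations ran from -0.0222 to 0.00705 in 6 pairs, in the count table from -0.0245 to 0.000787 in 3 pairs, and in the untreated TPM table the only pair gave 0.0318. With the replicate block, which fits the line or replicate number as an added factor, 1353 genes were called under BMP4 and 703 under LDN193189, and these are given beside the results they change.

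Alternatives were another scaling, other filters, pseudocounts of 0.1 and 5, limma without trend, tables fitted alone, the replicate block, DESeq2 1.42.0, a minimum fold change, each library left out in turn, and the other set tests. After the data were seen, edgeR on recovered reads, a fit without genes of chromosomes 6 and 8, and a fit without genes under 200 bases were added. The scripts were tested on simulated data with 200 genes changed and a dispersion of 0.01. For the mean of KO7 and KO8 against WT, over 13341 genes, edgeR recovered 71.6% of the genes changed 1.5-fold, 100% at 2-fold and 100% at 4-fold, with 8 false calls among 189. DESeq2 on the same contrast, over 16431 genes, recovered 52.2%, 94% and 100% at these folds, with 4 false calls. For the mean of the treated tables, over 12786 genes, limma recovered 100% at each fold, with 26 false calls among 226. For activin A alone it recovered 50.7%, 92.5% and 100%, with 14 false calls. For the activin interaction, over 12797 genes, it recovered 10.4%, 61.2% and 100%, with 4 false calls. For the untreated TPM table, over 12837 genes, it recovered 37.3%, 92.5% and 100%, with 11 false calls. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. The untreated and treated TPM tables were not joined in any test.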

Results

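HMCES binds DNA at abasic sites, and its gene was first described for binding to 5-hydroxymethylcytosine in embryonic stem cells. The series asked how loss of HMCES changes the balance between the transcription programmes of Nodal/activin signalling, which acts through SMAD2 and SMAD3, and of BMP signalling, which acts through SMAD1 and SMAD5. Steady-state RNA was sequenced in 26 libraries of mouse embryonic stem cells. The count table held 2 libraries each of untreated WT cells and of the knockout lines KO7 and KO8. A separate TPM table held 2 untreated WT and 2 untreated HMCES-KO libraries, and which knockout line these came from is not given in the sources used here. Each of 4 further TPM tables held 2 WT and 2 HMCES-KO libraries after 2 h with activin A, a ligand of the Nodal/activin receptors, with SB431542, an inhibitor of those receptors, with BMP4, or with LDN193189, an inhibitor of BMP receptors. Total counts per library, in units of 1000000 reads, were 9.57 to 13.5 in the count table. Recovered totals were 8.52 to 10.0 in the untreated TPM table, 4.39 to 4.89 under activin A, 4.57 to 5.55 under SB431542, 4.40 to 5.29 under BMP4 and 4.12 to 5.32 under LDN193189.

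The targeted gene, Hmces (mm10 chromosome 6, 87913976 to 87936613, plus strand), was lower in each HMCES-KO library than in each WT library of its table. In the count table the WT libraries had 297 and 356 CPM (counts scaled to 1000000 per library), the KO7 libraries 125 and 127, and the KO8 libraries 86.8 and 81.5. Relative to the WT mean of the table, KO7 stood at 38.1% and 38.8%, KO8 at 26.5% and 24.9%, and the untreated HMCES-KO libraries of the TPM table at 21.2% and 22.1%. After treatment the line labelled KO1 stood at 51.7% under activin A, 62.8% under SB431542, 64.1% under BMP4 and 61.6% under LDN193189, and the line labelled KO2 at 25.0%, 28.9%, 34.0% and 27.0%. Hmces fell by 1.67 in the mean of KO7 and KO8 (edgeR adjusted p = 2.4e-13), by 2.20 in the untreated TPM table (limma adjusted p = 2.2e-05) and by 1.27 in the mean of the treated tables (limma adjusted p = 0.00050). Within single treated tables limma called it only under activin A, where Hmces had a log2 fold change of -1.47 (adjusted p = 0.038). It lost that call without WT replicate 1 (limma adjusted p = 0.15), WT replicate 2 (0.15) or KO2 (0.26) of that table, without any 1 of the 6 WT libraries of the other treated tables (0.053 to 0.055) and with limma without trend (0.081). With the replicate block Hmces was also called under SB431542 at -1.23 (limma adjusted p = 2.0e-06), BMP4 at -1.09 (9.4e-06) and LDN193189 at -1.29 (4.0e-06), against 0.076, 0.14 and 0.13 without the block. Transcript level does not show how much HMCES protein was left, and no exon-level values were used here.

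**Figure D1:**
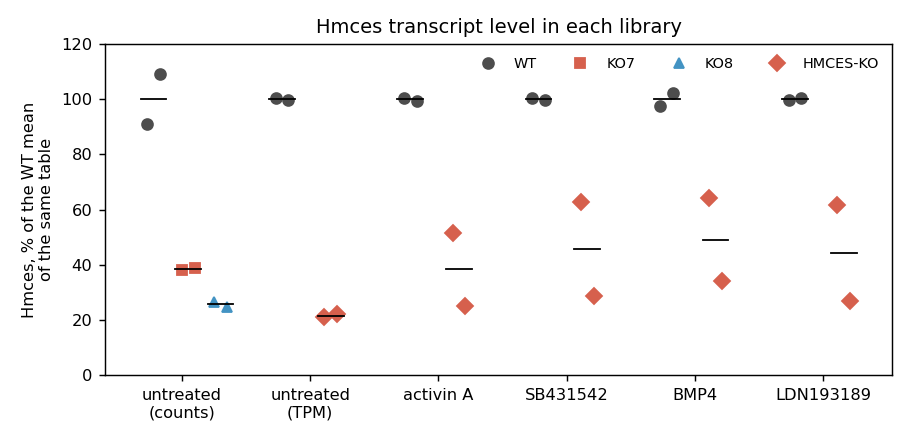
Hmces transcript level in each of the 26 libraries, as percent of the WT mean of the same table (horizontal lines are group means, and in the treated tables the left diamond is KO1 and the right one KO2). HMCES-KO libraries lay between 21.2% and 64.1%, below the lowest WT library at 90.9%.

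In untreated cells of the count table, the named genes with the largest falls included several known from the endoderm. Cubn (-2.88 ± 0.15), Amn (-2.54 ± 0.31) and Dab2 (-2.65 ± 0.13), which make up the endocytic machinery of the visceral endoderm, fell with the endoderm transcription factor Sox17 (-2.74 ± 0.34). Cyp26a1, which breaks down retinoic acid, fell by 3.77 ± 0.40, and the proteoglycan gene Srgn (-3.74 ± 0.19) and the forkhead factor gene Foxq1 (-3.06 ± 0.24) fell as well. H19, an imprinted noncoding RNA, fell by 3.05 ± 0.21, Ndufa4l2, a gene known to be induced by hypoxia, by 3.02 ± 0.22 and A2m by 2.56 ± 0.22. Among rises, Mirg (2.26 ± 0.20) and Rian (1.88 ± 0.07), noncoding RNAs of the imprinted Dlk1-Dio3 region, stood beside Aass (2.69 ± 0.13), which encodes a lysine-degrading enzyme, the Wnt receptor gene Ror1 (2.26 ± 0.39), the zinc finger factor Sall3 (2.07 ± 0.12) and Hhip (1.93 ± 0.43), an antagonist of hedgehog ligands. Dgkb (2.31 ± 0.40), Nlrp9b (1.99 ± 0.24), Sgo2b (1.94 ± 0.34) and Apol6 (1.93 ± 0.29) completed the set. For these 20 genes the edgeR adjusted p ran from 6.8e-13 for Rian to 0.0012 for Hhip, each with 4 HMCES-KO and 2 WT libraries that did not overlap. With the 4 HMCES-KO libraries as 1 group, Ror1 (adjusted p = 0.059), Apol6 (0.064), Nlrp9b (0.078) and Sox17 (0.094) were no longer called.

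Over all genes in that contrast, edgeR called 5476 of 13475, 2677 higher and 2799 lower in the mean of KO7 and KO8, of which 153 rose and 557 fell at least 2-fold. DESeq2 called 3587, and edgeR with the HMCES-KO libraries as 1 group called 1552.

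Endoderm markers formed the group with the lowest median. Of 15 measured members 14 fell and none rose, and 15 fell when adjusted over the list alone, with a median of -1.74. Col4a1 (-1.46 ± 0.07) and Col4a2 (-1.74 ± 0.09), the chains of basement membrane collagen, fell along with Dab2 and Cubn. The camera adjusted p was 9.9e-11, and the adjusted p = 0.172 with an estimated correlation. Hypoxia and glycolysis genes had 10 of 11 members lower, among them Egln3 (-1.89 ± 0.15), Bnip3 (-1.49 ± 0.16), Aldoa (-0.61 ± 0.06) and Hk2 (-0.45 ± 0.05), also 10 when adjusted over the list alone (median -0.50, camera adjusted p = 0.00072, adjusted p = 0.548 with an estimated correlation). In the integrated stress response list 6 of 10 members fell and none rose, and 7 fell when adjusted over the list alone. They included Asns (-0.80 ± 0.05), which makes asparagine, and Ddit4 (-0.96 ± 0.11) (median -0.35, camera adjusted p = 0.034, adjusted p = 0.548 with an estimated correlation). Without KO7 replicate 1 the camera adjusted p of this list was 0.074, and without KO8 replicate 1 it was 0.064. This list was called in KO8 (8 of 10 lower, 8 over the list alone, median -0.64, camera adjusted p = 0.0031, adjusted p = 0.460 with an estimated correlation) and not in KO7 (1 higher and 2 lower, 0.433). Neuroectoderm genes rose in 5 of 6 cases, 6 when adjusted over the list alone, with Pax6 at 1.66 ± 0.21, Tubb3 at 0.89 ± 0.06, Sox11 at 0.57 ± 0.09 and Nes at 0.48 ± 0.10 (median 0.53, camera adjusted p = 0.00081, adjusted p = 0.423 with an estimated correlation). With the HMCES-KO libraries as 1 group Nes (edgeR adjusted p = 0.21) and Asns (0.073) were not called, and camera did not call the stress response list (adjusted p = 0.083).

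Among Nodal/activin SMAD2/3 targets, 1 of 14 measured members rose and 5 fell in the count table, the same numbers when adjusted over the list alone. Smad7, the inhibitory SMAD that both pathways induce, fell by 0.96 ± 0.05 (edgeR adjusted p = 7.7e-12). Lefty1, a secreted Nodal antagonist, fell by 0.63 ± 0.07 (edgeR adjusted p = 4.8e-07), the Nodal co-receptor gene Tdgf1 by 0.54 ± 0.07 and Pmepa1, which restrains SMAD2 and SMAD3 activation, by 0.32 ± 0.06. Lefty2 fell by 0.22 ± 0.06 and Trh rose by 0.28 ± 0.06, while Nodal itself stood at -0.02 ± 0.05 (edgeR adjusted p = 0.79). The list had a median of -0.27 and a camera adjusted p of 0.034, with adjusted p = 0.423 with an estimated correlation and 0.064 without KO7 replicate 1. With the HMCES-KO libraries as 1 group the camera adjusted p was 0.059, and Tdgf1 (edgeR adjusted p = 0.076), Lefty2 (0.80) and Trh (0.24) were not called. Lefty1 and Lefty2 are neighbouring paralogues on chromosome 1 with similar coding sequences, so reads could be split between them.

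BMP SMAD1/5 targets moved in both directions in the count table. The Id genes, which encode inhibitors of basic helix-loop-helix factors and are direct BMP targets, were higher, with Id2 at 1.61 ± 0.13 (edgeR adjusted p = 1.1e-08), Id4 at 0.59 ± 0.14, Id3 at 0.36 ± 0.10 and Id1 at 0.28 ± 0.06. Smad7, Dusp9 (-0.66 ± 0.05), a phosphatase that acts on ERK, and the transcription factor Tbx3 (-0.42 ± 0.05) were lower. In total 4 of 13 rose and 3 fell, the same when adjusted over the list alone, with a median of -0.06 and a camera adjusted p of 0.794. Id3 lost its call without WT replicate 1 (edgeR adjusted p = 0.21) and without KO7 replicate 1 (0.051). With the HMCES-KO libraries as 1 group Id1 (adjusted p = 0.061), Id4 (0.054), Id3 (0.47) and Tbx3 (0.12) were not called.

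In the remaining lists camera called no shift in the mean of KO7 and KO8, although single members moved. Naive pluripotency genes split evenly, 5 of 15 higher and 5 lower, with Klf2 up (1.18 ± 0.05) and Klf4 down (-0.56 ± 0.04). Of 10 general pluripotency genes 5 rose and 1 fell. Of 10 formative and primed genes 2 rose, led by Zic2 (1.45 ± 0.09), and 1 fell. In the TGF-beta family of ligands, receptors and SMADs, 6 of 21 rose and 4 fell, 8 and 4 when adjusted over the list alone, with the ligand gene Bmp7 at -1.57 ± 0.17, a list median of 0.08, a mean of -0.03 and an upward direction in camera. Primitive streak and mesoderm genes gave 2 of 8 higher and 1 lower, 4 and 3 when adjusted over the list alone. Trophectoderm genes gave 1 of 8 higher and 1 lower, 2 and 3 over the list alone. Of 10 germline genes 3 fell, and of 15 p53 targets 7 fell, among them the cell-cycle inhibitor gene Cdkn1a (-0.62 ± 0.07) and the apoptosis gene Pmaip1 (-1.23 ± 0.10). Base excision repair and DNA demethylation genes gave 4 of 17 higher and 6 lower, Wnt targets 2 of 9 higher and 3 lower (3 and 3 over the list alone), and immediate early genes 1 of 10 higher and 3 lower. Fibroblast markers, which feeder cells would bring, gave 2 of 6 higher and 3 lower, with Vim at 0.54 ± 0.06, Thy1 at -1.52 ± 0.10 and Pdgfrb at -1.63 ± 0.17. The camera adjusted p of these 12 lists ran from 0.120 for germline genes to 0.794 for naive pluripotency. No member of the 2-cell-like list was measured in the untreated tables, and no mitochondrial transcript in any table.

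The knockout lines differed from each other in the count table. Trophectoderm markers were higher in KO8 than in KO7 (5 of 8 members, 6 over the list alone, median 1.11, camera adjusted p = 8.8e-05), as were p53 targets (9 of 15 higher and 1 lower, 11 and 1 over the list alone, median 0.27, camera adjusted p = 0.00026). Endoderm markers were lower in KO8 than in KO7 (8 of 15 lower and 1 higher, 11 and 2 over the list alone, median -0.89, camera adjusted p = 8.6e-05). With an estimated correlation the adjusted p was 0.263 for trophectoderm, 0.264 for p53 targets and 0.263 for endoderm. Against WT, 13 of 15 endoderm markers fell in KO7 and 15 in KO8, 14 and 15 over the list alone (medians -1.14 and -2.14, camera adjusted p = 4.3e-08 and 1.4e-11, adjusted p = 0.257 and 0.154 with an estimated correlation). In KO7, 10 of 15 p53 targets fell, 10 over the list alone (median -0.43, camera adjusted p = 0.00083), and 5 of 8 trophectoderm markers fell, 5 over the list alone (median -0.83, 0.045), each with adjusted p = 0.332 with an estimated correlation. Neither list was called by camera in KO8 (0.721 for p53 targets, 0.082 for trophectoderm). Camera lost trophectoderm in KO7 without WT replicate 2 (0.12), KO7 replicate 2 (0.051), KO8 replicate 1 (0.069) or KO8 replicate 2 (0.069) and with the stricter filter (0.24). Integrated stress response genes were lower in KO8 than in KO7 (7 of 10 lower and 1 higher, also over the list alone, median -0.47, camera adjusted p = 0.0065, adjusted p = 0.553 with an estimated correlation). Of the SMAD targets, Lefty2 rose in KO7 (0.27 ± 0.07, edgeR adjusted p = 0.0028) and fell in KO8 (-0.71 ± 0.07, 1.8e-07), and Smad6, an inhibitory SMAD induced by BMP, fell in KO7 (-0.57 ± 0.15, 0.0046) and rose in KO8 (0.55 ± 0.13, 0.0027). Id2 was at 1.61 in both lines, ± 0.14 in KO7 and ± 0.15 in KO8. Lefty2 in KO7 lost its call without KO7 replicate 1 (edgeR adjusted p = 0.091), and Smad6 in KO7 lost it with DESeq2 (DESeq2 adjusted p = 0.051).

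Against WT, edgeR called 5149 genes in KO7 (2558 higher, 2591 lower) and 5248 in KO8 (2594 higher, 2654 lower), and 3797 genes differed between KO8 and KO7 (1869 higher in KO8, 1928 lower). DESeq2 called 3287, 3290 and 2301. Leaving out 1 library of a line lowered the KO7 count to 3088 without replicate 1 and 3290 without replicate 2, and the KO8 count to 3230 and 3312. The KO8 against KO7 count fell to 2012 and 2261 without KO7 replicates 1 and 2 and to 2264 and 2213 without KO8 replicates 1 and 2. Both comparisons with WT share its 2 libraries, and they were not split, since that would leave 1 WT library for each line. In total 3048 genes were called in both lines, 1377 higher in both, 1374 lower in both and 297 in opposite directions, where independent lists would give 492, 510 and 1003. The fold changes of both lines correlated across genes at 0.568, against 0.492 in 20 simulations without any effect, and their covariance was 0.177 against 0.0191. Part of this overlap may come from the shared WT libraries.

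In the untreated TPM table, 6 Nodal/activin targets and 2 BMP targets rose. Id2 rose by 2.02 ± 0.06 and Id1 by 1.28 ± 0.04 (limma adjusted p = 8.9e-05 for each). Lefty1 rose by 1.67 ± 0.06 (limma adjusted p = 0.00023), Lefty2 by 1.44 ± 0.05 (0.00031) and Trh, which encodes thyrotropin-releasing hormone, by 1.21 ± 0.03 (7.6e-05). Skil (0.33 ± 0.04) and Otx2 (0.36 ± 0.08) rose as well. In total 6 of 14 Nodal/activin targets rose and none fell, 7 and 1 when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.00023, adjusted p = 0.516 with an estimated correlation). Otx2 lost its call without WT replicate 1 (limma adjusted p = 0.13), WT replicate 2 (0.11) or HMCES-KO replicate 2 (0.11). BMP targets gave 2 of 13 higher and 2 lower, 3 and 3 over the list alone, with Tbx3 at -0.65 ± 0.04 and Dusp9 at -0.36 ± 0.05 (camera adjusted p = 0.111), and limma lost Dusp9 without WT replicate 1 (adjusted p = 0.060). With limma without trend Skil (adjusted p = 0.074), Otx2 (0.078) and Dusp9 (0.085) were not called.

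Neuroectoderm genes rose in 4 of 7 cases in that table, 6 when adjusted over the list alone, among them Sox11 (0.72 ± 0.08), a neural transcription factor, and Sox1 (0.74 ± 0.13) (median 0.72, camera adjusted p = 0.00012). Of 12 endoderm genes 3 fell, 3 also when adjusted over the list alone, namely the secreted matrix protein gene Sparc (-0.43 ± 0.05), the laminin gene Lama1 (-0.65 ± 0.08) and the transcription factor Gata6 (-0.93 ± 0.22) (median -0.31, camera adjusted p = 0.0085). Of 10 germline genes 3 fell, 5 when adjusted over the list alone, among them Tex19.1 (-0.47 ± 0.06) and Dazl (-1.11 ± 0.23) (median -0.42, camera adjusted p = 0.018). With an estimated correlation each of these lists had an adjusted p = 0.516. Camera lost the germline list without WT replicate 1 (adjusted p = 0.13) or HMCES-KO replicate 1 (0.14). Limma lost Gata6 without any 1 of the 4 libraries (0.063 to 0.20), Sox1 without WT replicate 1 (0.062) or 2 (0.068) Dazl without WT replicate 1 (0.10) or 2 (0.12) and Tex19.1 without WT replicate 1 (0.052) or 2 (0.053). Limma without trend did not call Sparc (0.062), Sox1 (0.062), Tex19.1 (0.053) or Dazl (0.071), and quantile normalization lost Gata6 (0.066).

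The other genes with the largest changes in that table were small RNA genes, whose short length turns few reads into a large TPM and whose reads may belong to an overlapping host gene, so they are given as uncertain. Mir2861 (2.68 ± 0.29), AF357426 (2.65 ± 0.35), Snord67 (2.47 ± 0.29) and Snord33 (2.16 ± 0.31) were higher, and Mir7003 (-4.44 ± 0.20), Mir1950 (-3.94 ± 0.21), Mir668 (-3.36 ± 0.20), Mir7036b (-3.25 ± 0.45) and Mir7028 (-3.23 ± 0.45) were lower. Over all genes limma called 2128 of 13314, 772 higher and 1356 lower, and edgeR on recovered reads called 3587. Limma without trend called 339, and AF357426 (adjusted p = 0.066), Snord33 (0.069), Mir7036b (0.064) and Mir7028 (0.064) were not among them. The share of calls that were higher was 36.3%, and it was 49.6% with median ratio scaling, 47.0% with quantile normalization and 51.0% with edgeR on recovered reads. It was 24.5% without genes of chromosomes 6 and 8, so it depended on these chromosomes as well as on the scaling. Without WT replicate 1 limma called 619 genes, and without WT replicate 2 it called 651.

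Across the treated tables, Id2 (1.66 ± 0.11) was again among the genes with the largest rise on the BMP list, and endoderm markers were again lower. The eye and forebrain factor Vax2 (2.37 ± 0.44), the imprinted retrotransposon-derived gene Rtl1 (1.91 ± 0.21) and Gap43 (1.54 ± 0.12), a growth cone protein gene, rose in the mean of the treated tables, with Fam166a (2.50 ± 0.14), Igsf23 (1.70 ± 0.19) and the metalloprotease gene Mep1b (1.56 ± 0.17). Peg10, another imprinted retrotransposon-derived gene, fell by 1.70 ± 0.15, Hbegf, a ligand of the EGF receptor, by 1.73 ± 0.13, and Ripply3, a transcriptional repressor, by 1.71 ± 0.23. Syce3 (-2.10 ± 0.33) and Rec114 (-1.89 ± 0.17), both genes of meiotic chromosomes, fell as well, with Tesc (-1.93 ± 0.23), Tmx2 (-1.86 ± 0.17), Kbtbd11 (-1.86 ± 0.12), Ankrd33b (-1.66 ± 0.13) and Ttc5 (-1.59 ± 0.21). Psma5 (2.07 ± 0.25) may share reads with similar sequences elsewhere, which was not examined here, and Pet100 (1.82 ± 0.17) and Atp5mpl (1.60 ± 0.12) are short, so these 3 are uncertain. The limma adjusted p of these genes ran from 1.2e-07 for Fam166a to 0.0011 for Vax2, with 8 HMCES-KO libraries against 8 WT libraries without overlap. These 8 HMCES-KO libraries were the lines KO1 and KO2 measured once in each table, and the fit took them as separate. The p-values and the number of calls therefore do not measure the spread between knockout lines. Limma called 4353 of 12608 genes, 1737 higher and 2616 lower, and edgeR on recovered reads called 4517. The share of calls that were higher was 39.9%, and it was 48.5% with median ratio scaling, 49.5% with quantile normalization and 49.2% with edgeR on recovered reads, so the excess of falls depended on the scaling.

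BMP targets rose in 6 of 15 cases and fell in 2 in the mean of the treated tables, 9 and 2 when adjusted over the list alone, with a median of 0.50 (camera adjusted p = 0.019, adjusted p = 0.182 with an estimated correlation). Id3 (0.85 ± 0.10), Id1 (0.50 ± 0.08), Smad6 (0.85 ± 0.25), Msx1 (0.72 ± 0.23) and Bambi (0.26 ± 0.09), a pseudoreceptor, rose beside Id2, while Smad7 (-0.92 ± 0.11) and Dusp9 (-0.69 ± 0.14) fell. Smad6 was higher in KO2 than in KO1 in each table. In reads scaled over the shared genes, Smad6 under SB431542 stood at 7.76 in KO1 and 27.3 in KO2, against 9.12 and 8.53 in WT. Under LDN193189 it stood at 6.49 in KO1 and 17.9 in KO2, against 6.31 and 5.51 in WT. Under activin A and BMP4 each line stood above both WT libraries. Limma lost Bambi (adjusted p = 0.054 to 0.10) without any 1 library except WT replicate 1 and KO2 under activin A, WT replicate 1 under SB431542 and KO1 under LDN193189. Limma also called Msx2 (0.55, adjusted p = 0.042) with the replicate block. Limma lost Msx1 (0.051 to 0.066) without WT replicate 2 or KO2 under activin A, WT replicate 2 or KO1 under SB431542, WT replicate 1 or KO2 under BMP4, and WT replicate 2 or KO1 under LDN193189. Nodal/activin targets gave 6 of 16 higher and 4 lower, the same over the list alone, with Tdgf1 at 0.78 ± 0.14 (limma adjusted p = 0.00095), Pmepa1 at -0.43 ± 0.07 (0.00048) and a camera adjusted p of 0.329.

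Of 15 endoderm markers 7 fell and none rose in the same contrast, among them Col4a2 (-1.11 ± 0.14) and Gata6 (-1.17 ± 0.23) (median -0.49, camera adjusted p = 0.0031, adjusted p = 0.168 with an estimated correlation). Of 15 p53 targets 10 fell, 11 when adjusted over the list alone, led by Trp53inp1 (-1.12 ± 0.09), with the p53 antagonist gene Mdm2 at -0.39 ± 0.05 (median -0.34, camera adjusted p = 0.0045, adjusted p = 0.182 with an estimated correlation). Hypoxia and glycolysis genes fell in 7 of 11 cases, also over the list alone (Aldoa -0.76 ± 0.06, median -0.36), general pluripotency genes rose in 5 of 10 (Gdf3 0.59 ± 0.04, Pou5f1 0.18 ± 0.04, median 0.12), and formative and primed genes rose in 5 of 10 and fell in 1 (Zic2 1.48 ± 0.07, Dnmt3a 0.59 ± 0.08, Etv4 -0.61 ± 0.04, median 0.41). The camera adjusted p was 0.019 for each of the last 3 lists. With an estimated correlation the adjusted p was 0.182 for hypoxia, 0.182 for general pluripotency and 0.320 for the formative list, and camera lost the formative list without the LDN193189 library of KO2 (adjusted p = 0.054) and general pluripotency under quantile normalization (0.15). Zscan4d, the only 2-cell-like gene measured, stood at -0.28 ± 0.30.

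**Figure D2:**
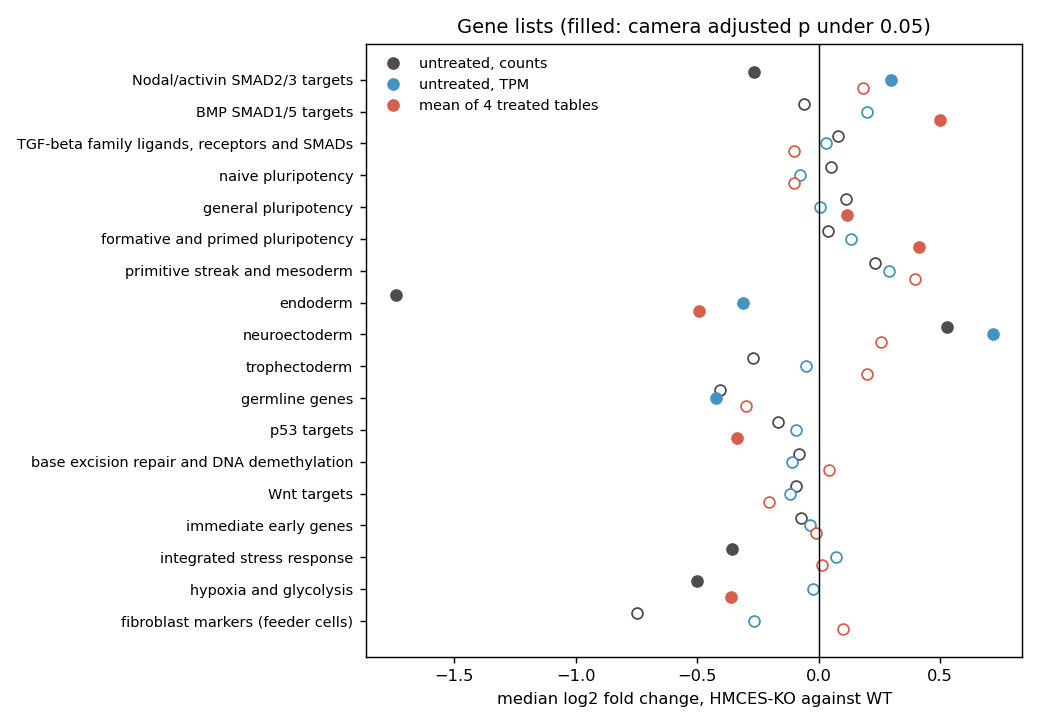
Median log2 fold change of HMCES-KO against WT for each gene list with at least 3 measured members, in the count table, the untreated TPM table and the mean of the treated tables, with filled circles for a camera adjusted p under 0.05 at the preset correlation. Endoderm medians were -1.74, -0.31 and -0.49, and Nodal/activin medians -0.27, 0.30 and 0.18.

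Within single treatments, Id2 rose in HMCES-KO against WT each time, and other SMAD targets passed the test in some tables only. Under activin A, Lefty2 (1.33 ± 0.21, limma adjusted p = 0.0021), Tdgf1 (1.57 ± 0.28, 0.0038) and Lefty1 (1.94 ± 0.39, 0.0073) were among the 4 of 16 Nodal/activin targets that rose, 7 when adjusted over the list alone (camera adjusted p = 0.010, adjusted p = 0.170 with an estimated correlation), and Id2 rose by 2.29 ± 0.22. Under SB431542, Smad7 fell by 1.58 ± 0.21 (limma adjusted p = 0.00070) and Pmepa1 by 0.69 ± 0.14 (0.0077), while Id2 (1.72 ± 0.22) and Id3 (1.02 ± 0.19) rose. Under BMP4, Id1 (1.55 ± 0.15, limma adjusted p = 0.00026), Id2 (1.43 ± 0.22, 0.0031) and Id3 (1.28 ± 0.19, 0.0031) rose, 3 of 15 BMP targets and 4 over the list alone (camera adjusted p = 0.0026, adjusted p = 0.151 with an estimated correlation), and no Nodal/activin target was called by limma. Under LDN193189, Smad7 fell by 1.18 ± 0.21 (limma adjusted p = 0.012) and Id2 rose by 1.21 ± 0.22 (0.012). With the replicate block limma also called Lefty1 (-1.10, adjusted p = 0.018), Skil (-0.96, 0.0047) and Trh (0.48, 0.020) under LDN193189, and Fgf8 (2.25, 0.049) and Mixl1 (1.45, 0.027) under activin A. Whether these effects differ between all 4 treatments was not tested, apart from the interactions of ligand and inhibitor. Limma lost Lefty1 under activin A without WT replicate 2 (0.057) or KO2 (0.055). It lost Pmepa1 under SB431542 without WT replicate 1 (0.081) or KO2 (0.053) and Id3 without WT replicate 2 (0.060). Under LDN193189 it lost Smad7 without WT replicate 1 (0.086) or 2 (0.11) and Id2 without WT replicate 2 (0.15). With each table fitted alone limma did not call Id2 or Id3 under BMP4 (0.061 for each) or Smad7 (0.091) or Id2 (0.16) under LDN193189.

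Beyond SMAD targets, the named genes of single treatments were partly shared. Under activin A, Snrpf (2.84 ± 0.31), Psma5 (2.70 ± 0.50, uncertain for the same reason as in the treated mean) and Glod5 (2.45 ± 0.44) rose, and Nppb (-2.76 ± 0.49), which encodes a natriuretic peptide, Crybg2 (-2.63 ± 0.41) and Ripply3 (-2.51 ± 0.46) fell. Under SB431542, Fam166a (2.80 ± 0.28), Ptprcap (2.57 ± 0.39) and Rtl1 (2.54 ± 0.42) rose, and Cox4i2 (-2.72 ± 0.30), a hypoxia-responsive subunit gene of cytochrome c oxidase, the ligand gene Wnt6 (-2.64 ± 0.41) and Hacd2 (-2.34 ± 0.40) fell. Fam166a also rose under BMP4 (2.27 ± 0.28) and LDN193189 (2.53 ± 0.28), where Rec114 fell by 2.62 ± 0.35. The limma adjusted p of these genes ran from 0.00015 for Fam166a under SB431542 to 0.0045 for Psma5 under activin A. Under LDN193189, Fam166a (0.068) and Rec114 (0.12) were not called with the table fitted alone. The other named genes lost their limma call without at least 1 library of their own table (adjusted p = 0.0525 to 0.27), namely Vrtn, Tarm1 and Mlana under activin A, Vrtn, Wfdc10 and Fkbp6 under SB431542, Vax2, Myl7, Fam183b, Tmsb15b1, Tesc, Med29, Glo1 and Ttc5 under BMP4, and Olig3, Psma5, Igsf23, Wfdc10, Gstp1, Tm4sf5 and Tesc under LDN193189.

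Further lists moved within single treatments at the preset correlation of camera. Of 15 p53 targets 7 fell under activin A and 6 under SB431542, 10 and 6 when adjusted over the list alone (camera adjusted p = 0.00013 and 0.0057). Hypoxia and glycolysis genes fell in 6 of 11 cases under activin A and 7 of 11 under SB431542, 7 and 7 over the list alone (0.0027 and 0.0057). Endoderm markers fell in 2, 3 and 1 of 15 cases under activin A, SB431542 and BMP4, 5, 3 and 1 over the list alone (0.0038, 0.014 and 0.0079). Formative and primed genes rose in 4 of 10 cases and fell in 1 under activin A, and rose in 2 and fell in 1 under SB431542 (0.0027 and 0.018), and general pluripotency genes rose in 2 of 10 under SB431542 and in 2 of 10 under LDN193189 (0.047 and 0.022). With an estimated correlation no such list was called, with adjusted p = 0.11 to 0.238 under activin A, 0.144 to 0.416 under SB431542, 0.151 under BMP4 and 0.174 under LDN193189. Camera lost the endoderm list under BMP4 without KO1 (0.12) and general pluripotency under LDN193189 without WT replicate 1 (0.051) and under quantile normalization (0.19). It lost general pluripotency under SB431542 without WT replicate 1 (0.093), WT replicate 2 (0.062) or KO2 (0.099) of that table, without most libraries of the other tables (0.052 to 0.058), with the replicate block (0.056) and under quantile normalization (0.15).

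In numbers of genes, limma called 1529 under activin A (643 higher, 886 lower), 1531 under SB431542 (682 higher, 849 lower), 798 under BMP4 (268 higher, 530 lower) and 289 under LDN193189 (100 higher, 189 lower). With the replicate block it called 1353 under BMP4 and 703 under LDN193189, and with each table fitted alone 41 and 1. Without 1 library of the table the counts fell to 577 and 508 (WT replicates 1 and 2) and 699 and 708 (KO1 and KO2) under activin A, and to 535, 439, 629 and 866 under SB431542. They were 158 and 133 without the WT replicates and 322 without KO2 under BMP4, and 53, 18, 127 and 493 under LDN193189, where leaving out the SB431542 library WT replicate 1 or 2 gave 176 or 175. The share of calls that were higher was 33.6% under BMP4 and 34.6% under LDN193189. It was 45.6% and 49.6% with median ratio scaling, 43.8% under BMP4 with quantile normalization and 49.0% under LDN193189 with edgeR on recovered reads.

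Activin A against SB431542 asked which genes followed Nodal/activin receptor activity in each genotype. In WT, Lefty1 was higher under activin A by 3.45 ± 0.39 (limma adjusted p = 0.0091) and Smad7 by 1.52 ± 0.21 (0.038), and these were the 2 genes called. In HMCES-KO, Lefty1 was higher by 5.82 ± 0.39 (1.7e-05), Smad7 by 2.70 ± 0.21 (4.9e-05), Lefty2 by 2.50 ± 0.21 (9.6e-05) and Pmepa1 by 1.03 ± 0.14 (0.0093). Hrh3, a histamine receptor gene, was higher by 1.92 ± 0.32 (0.044) and the growth factor gene Fgf15 by 1.57 ± 0.27 (0.046), while the glutaredoxin gene Glrx3 was lower (-1.78 ± 0.25, 0.0093) and Bmp4 had -0.49 ± 0.08 (0.028), among 13 genes called, 11 of them higher. In reads per 1000000 reads of the shared genes (mean ± SD, n = 2), Lefty1 stood at 33.5 ± 1.13 in WT and 136 ± 18.7 in HMCES-KO under activin A, and at 2.53 ± 0.178 and 1.76 ± 0.445 under SB431542. Smad7 stood at 290 ± 9.08 and 227 ± 0.460 under activin A and at 101 ± 4.37 and 35.3 ± 16.9 under SB431542. Treatment and table are the same split here, so a difference between tables of another origin cannot be told apart from the treatment.

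The interaction set the difference between activin A and SB431542 in HMCES-KO against that in WT, without untreated cells. It had 3 Nodal/activin targets when adjusted over the list alone. These were Lefty2 (1.44 ± 0.30, limma adjusted p = 0.0056), Lefty1 (2.37 ± 0.56, 0.0072) and Smad7 (1.18 ± 0.30, 0.0084, and 0.024 over the BMP list). For Smad7, HMCES-KO stood below WT under activin A too, so its larger difference came from its lower level under SB431542. Over all genes limma called 0, with 477 genes at an unadjusted p under 0.05, and edgeR on recovered reads called 0, and the adjusted p over all genes was 0.73 for Lefty2 and 0.76 for Lefty1 and Smad7. The Nodal/activin list as a whole had a median of 0.39 in the interaction (camera adjusted p = 9.1e-07, adjusted p = 0.0491 with an estimated correlation, and a fry adjusted p of 0.0685). In WT 2 of 16 members were called higher, and 4 were higher and 1 lower over the list alone (median 0.12, camera adjusted p = 0.00049, adjusted p = 0.199 with an estimated correlation, and a fry adjusted p of 0.092). In HMCES-KO 4 of 16 were higher, 6 over the list alone (median 0.46, camera adjusted p = 6.4e-16, adjusted p = 0.0030 with an estimated correlation). The BMP list was not called by camera in WT (adjusted p = 0.183), in HMCES-KO (0.078) or in the interaction (0.799). With the replicate block it was called in HMCES-KO (camera adjusted p = 0.024), as with a pseudocount of 5 (0.029), and limma with the block called Skil there (0.98, adjusted p = 0.026). With edgeR on recovered reads Lefty1 had 0.069 over the list alone in the interaction. In WT limma lost Lefty1 without any 1 of the 4 WT libraries compared (0.18 to 0.23) and Smad7 without any 1 of these (0.28 to 0.83) or any 1 of the BMP4 and LDN193189 WT, BMP4 HMCES-KO and activin A HMCES-KO libraries (0.082 to 0.10). In HMCES-KO it lost Pmepa1 without KO2 under activin A (0.16) or without KO1 (0.097) or KO2 (0.13) under SB431542. The HMCES-KO count was 5 and 3 without KO1 and KO2 under activin A and 3 and 4 without them under SB431542, with Hrh3 (0.20 to 0.37), Fgf15 (0.16 to 0.48) and Bmp4 (0.16 to 0.39) lost without any 1 of the 4, and Glrx3 (0.13 to 0.18) without each of them but KO1 under activin A.

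BMP4 against LDN193189 asked the same of BMP receptor activity. In WT, Id2 was higher under BMP4 by 2.00 ± 0.22 (limma adjusted p = 0.0056), Id3 by 1.37 ± 0.19 (0.033) and Id1 by 1.13 ± 0.15 (0.032), and Btf3 had -0.98 ± 0.15 (0.046), 4 genes in all. In HMCES-KO, Id1 was higher by 2.53 ± 0.15 (4.4e-06), Id3 by 2.13 ± 0.19 (0.00032) and Id2 by 2.22 ± 0.22 (0.00056), and these were the 3 genes called. In reads per 1000000 reads of the shared genes (mean ± SD, n = 2), Id1 stood at 529 ± 2.65 in WT and 1619 ± 421 in HMCES-KO under BMP4, and at 241 ± 15.8 and 276 ± 59.3 under LDN193189. Of BMP targets 3 of 15 were higher in WT, 3 over the list alone (camera adjusted p = 2.0e-05, adjusted p = 0.0692 with an estimated correlation), and 3 of 15 in HMCES-KO, 5 over the list alone (4.1e-13, adjusted p = 0.0042 with an estimated correlation). Nodal/activin targets had a median of 0.52 in HMCES-KO (camera adjusted p = 8.1e-09, adjusted p = 0.0122 with an estimated correlation), with Smad7 (1.05 ± 0.21), Bambi (0.91 ± 0.18) and Lefty1 (1.24 ± 0.39) called over the list alone and none over all genes. In WT limma lost Id1 (0.21 to 0.42) and Id3 (0.21 to 0.57) without any 1 of the 4 WT libraries compared, and Id2 without BMP4 replicate 1 (0.18) or 2 (0.11) or LDN193189 replicate 2 (0.21). It called 0 genes without either BMP4 WT library or without LDN193189 WT replicate 2, and 1 without LDN193189 WT replicate 1. With median ratio scaling, quantile normalization or edgeR on recovered reads Btf3 was not called, and 100% of the WT calls were higher, against 75% before. Limma with the replicate block did not call Btf3 either (adjusted p = 0.051). In HMCES-KO limma called 12 genes without KO1 under LDN193189.

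In the BMP interaction, Id1 (1.40 ± 0.22, limma adjusted p = 0.00031) and Bambi (0.93 ± 0.26, 0.024) passed when adjusted over the BMP list alone, and Id3 had 0.76 ± 0.27 (0.079). Over all genes limma called 0, with 624 genes at an unadjusted p under 0.05, edgeR on recovered reads called 1, and the adjusted p of Id1 over all genes was 0.26. The BMP list had a median of 0.27 (camera adjusted p = 0.014, adjusted p = 0.439 with an estimated correlation) and the Nodal/activin list a median of 0.20 (0.043, adjusted p = 0.523 with an estimated correlation). Limma lost Bambi without BMP4 WT replicate 1 (0.070) or 2 (0.067), BMP4 KO1 (0.054), LDN193189 WT replicate 1 (0.060) or 2 (0.082) or LDN193189 KO1 (0.094). Camera lost the BMP list without BMP4 WT replicate 2 (0.052), BMP4 KO2 (0.28) or LDN193189 KO1 (0.17), and the Nodal/activin list without BMP4 WT replicate 1 (0.25) or 2 (0.052), BMP4 KO2 (0.30), LDN193189 WT replicate 1 (0.28) or LDN193189 KO1 (0.31). With fry these lists had adjusted p of 0.18 and 0.32, and without LDN193189 KO1 limma called 8 genes.

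**Figure D3:**
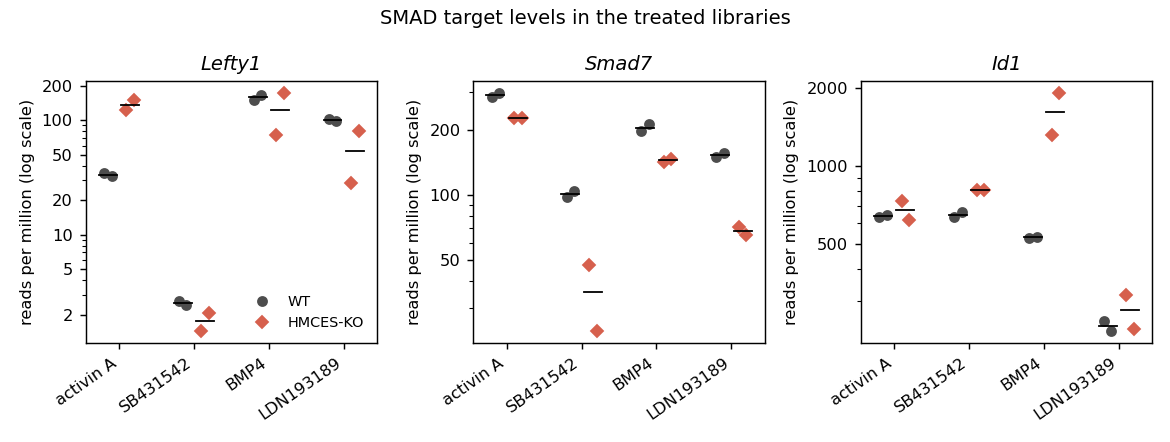
Levels of Lefty1, Smad7 and Id1 in each treated library, in reads per 1000000 reads of the shared genes on a log axis, with horizontal lines for group means (n = 2, left HMCES-KO point KO1 and right one KO2). Lefty1 under activin A stood at 32.7 and 34.4 in WT and at 122 and 149 in HMCES-KO, and Id1 under BMP4 at 528 and 531 in WT and at 1321 and 1916 in HMCES-KO.

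Genes of chromosomes 6 and 8 moved together over long stretches, and members of the gene lists that lie there were not set apart. From 30 Mb to the end of chromosome 8 (mm10), the 503 genes with a mean count of at least 50 had a median log2 fold change of 0.37 in KO7, with 85.9% of them above 0, and of 0.00 in KO8. Over the same stretch the median was 0.25 in the untreated TPM table, 0.26 in the treated KO1 libraries and 0.00 in the treated KO2 libraries. Below 30 Mb it was -0.09 in KO7, 0.25 in the untreated TPM table and -0.17 in treated KO1. On chromosome 6, which carries Hmces, genes from 60 Mb had a median of -0.36 in KO7, -0.24 in KO8, -0.37 in treated KO1, -0.11 in treated KO2 and 0.04 in the untreated TPM table, while genes below 60 Mb had -0.02 in KO7 and -0.20 in KO8. Genes of all other chromosomes had medians of 0.02 in KO7, 0.02 in KO8, -0.06 in the untreated TPM table, -0.07 in treated KO1 and -0.03 in treated KO2. Without genes of chromosomes 6 and 8 edgeR called 4720 genes in the mean of KO7 and KO8, and limma 1590 in the untreated TPM table and 3912 in the mean of the treated tables.

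**Figure D4:**
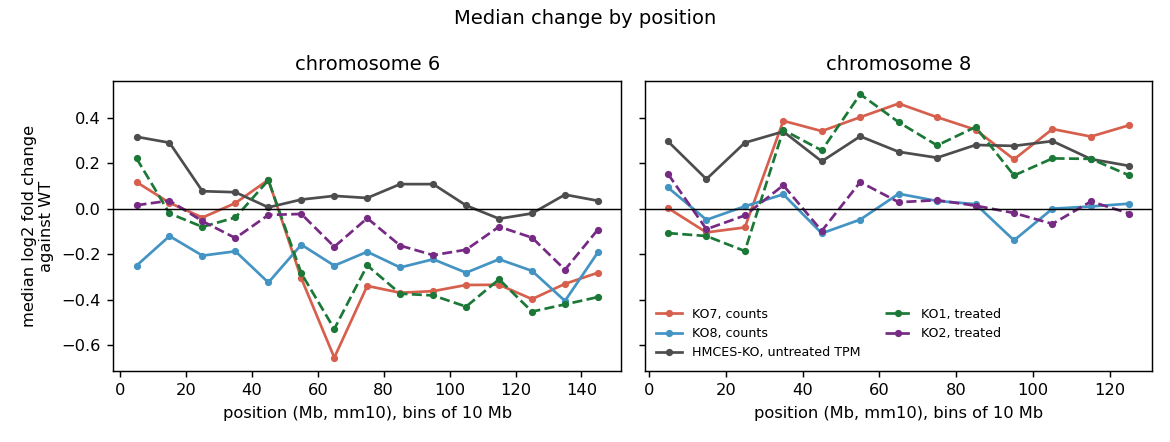
Median log2 fold change against WT in bins of 10 Mb along chromosomes 6 and 8 (mm10) for both untreated lines of the count table, the untreated TPM table and both treated lines. On chromosome 8 the medians from 30 Mb were 0.37 in KO7, 0.25 in the untreated TPM table and 0.26 in treated KO1, against 0.00 in KO8.

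The 3 data sets shared part of their calls. The count table and the untreated TPM table called 1115 genes in common, 322 higher in both, 410 lower in both and 383 in opposite directions, where independent lists would give 156, 269 and 426. The count table and the mean of the treated tables shared 2153 (728 higher, 851 lower, 574 opposite, against 358, 537 and 897), and the untreated TPM table and the treated mean shared 926 (225 higher, 462 lower, 239 opposite, against 101, 262 and 326). Lefty1 was among the genes with opposite directions, at -0.63 in the count table and 1.67 in the untreated TPM table, as was Lefty2, at -0.22 and 1.44.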

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

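The differences listed first were not foreseen when the comparisons were fixed, and the tests weighed after them were chosen partly before and partly after the results were seen, as given in each case. The lines KO7 and KO8 differed at 3797 genes when untreated (edgeR). Among SMAD targets, Lefty2 was lower in KO8 than in KO7 (-0.98, edgeR adjusted p = 1.5e-09), while Otx2 (0.74, 3.6e-05) and Smad6 (1.12, 3.9e-06) were higher. The cause was not tested. In the difference between ligand and inhibitor, HMCES-KO exceeded WT for Lefty1 by 2.37, Lefty2 by 1.44 and Smad7 by 1.18 under activin A against SB431542. It exceeded WT for Bambi by 0.93 and for Id1 by 1.40 under BMP4 against LDN193189, each with limma and adjusted over its list alone. The level of Smad7 was lower in HMCES-KO than in WT under activin A and under SB431542. The cause was not tested.

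Over the 4 treated tables, 4353 genes differed between HMCES-KO and WT. Of the 648 ways to split the 16 libraries 2 against 2 within each table, 100 were tried, and 1 split, the real one, called as many genes, the highest other reaching 1916 (limma). With the replicate block the count was 4934. The splits took libraries of the same line in different tables as separate.

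Genes with opposite directions in the count table and the untreated TPM table numbered 383, and whether a gene's changes differed between both data sets was not tested for each gene. Lefty1 was -0.50 in KO7, -0.76 in KO8 and 1.67 in the TPM table, and Lefty2 0.27, -0.71 and 1.44, so for Lefty1 neither line had the direction of the TPM table, whose HMCES-KO columns are named K81 and K82 without a line being stated. Swapped genotype labels would turn the strongest genes of the count table around, and these had a median of 0.28 in the same direction (chosen after the result was seen). The TPM scaling did not account for the pattern, since edgeR on whole reads moved the median of all genes by only 0.056. With it 95.3% stayed opposite (chosen before the result was seen), but after so small a shift few genes could turn around. A difference between the WT cultures alone could not be told from one between the HMCES-KO cultures, with a ratio of 0.878 (chosen after the result was seen), and culture conditions at harvest are not given in the sources used here.

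The joint shift of genes on chromosomes 6 and 8 was weighed against a changed dose of a chromosome region in part of the cells. In KO7 genes of the chromosome 8 block below their median mean count had a median of 0.262 and those above it 0.418. Genes of other chromosomes had 0.02 in KO7, so each part of the block was raised. The gap between the parts left this test undecided (chosen after the result was seen). In KO7 the shift was not confined to the surroundings of Hmces, because chromosome 6 genes more than 20 Mb away still had a median of -0.25 (chosen after the result was seen). The profile was known when this test was chosen, and it cannot exclude a larger change of chromosome 6 that came with the edit. For the chromosome 8 block in KO7, base composition, gene length and read depth were excluded. There 497 genes of other chromosomes matched to the block for them had a median of 0.014 (chosen before the result was seen). No such matching was done for the shift on chromosome 6. DNA copy number was not analysed here.

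The fall of endoderm markers in untreated cells may come from fewer endoderm-like cells in the knockout cultures rather than from a change within each cell. Further markers of extraembryonic endoderm, listed after the data were seen but leaving out genes with known values, had a median of -1.56, as fewer such cells would need (chosen before their values were seen). Of 14 listed, 9 were measured and 7 fell, among them Ctsh (-4.19), Aqp8 (-3.18), Ihh (-2.03) and Hnf4a (-1.56). These named genes had low WT levels, from 1.18 CPM for Ihh to 4.51 for Hnf4a. Falls were smaller for Lrp2 (-0.62, WT 56.5 CPM) and F3 (-0.40, 8.96), Foxa1 was not called (0.07), and Apoe rose (0.26, 556). The median thus rests on genes with low levels. Neuroectoderm genes had a median of 0.53, so the fall was not shared by markers of every differentiated type (chosen after the result was seen). That median was known when the test was chosen and covers only that lineage, so it cannot exclude fewer cells of other types. A change within each cell and an effect of HMCES itself stay open and were not tested, since single cells were not analysed here and no rescue was used here.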

How the results depend on the processing

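Numbers of called genes moved by more than 1.5 times under these settings. With a minimum 2-fold change there were 877 genes in KO7, 890 in KO8, 710 in the mean of both, 715 between KO8 and KO7, 451 under activin A, 420 under SB431542, 170 under BMP4, 72 under LDN193189, 219 in the treated mean, 7 for activin A against SB431542 in HMCES-KO and 212 in the untreated TPM table. DESeq2 called 3287 in KO7, 3290 in KO8, 3587 in their mean and 2301 between the lines, and edgeR with the HMCES-KO libraries as 1 group called 1552. Limma without trend called 443 under BMP4, 86 under LDN193189, 339 in the untreated TPM table, 3 for activin A against SB431542 in HMCES-KO, and 0 for each ligand contrast in WT. With each table alone limma called 41 under BMP4 and 1 under LDN193189, and with the 2 tables alone 1 for activin A and 0 for BMP4 in WT. A pseudocount of 0.1 gave 1 for activin A in WT, and no filter gave 1311 in the untreated TPM table. The replicate block gave 1353 under BMP4 and 703 under LDN193189. EdgeR on recovered reads called 3587 in the untreated TPM table, 5 for BMP4 against LDN193189 in HMCES-KO and 1 in the BMP interaction.

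Leaving out 1 library at a time gave 3088 to 6036 genes in KO7, 3230 to 6186 in KO8, 2012 to 5090 between the lines, 508 to 1781 under activin A, 439 to 1784 under SB431542, 133 to 1085 under BMP4, 18 to 493 under LDN193189 and 619 to 2418 in the untreated TPM table. The ligand contrasts gave 0 to 3 for activin A in WT, 3 to 12 in HMCES-KO and 0 to 2 for the interaction, and 0 to 5, 3 to 12 and 0 to 8 for BMP4.

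Among genes, Utf1 turned around in the treated mean under quantile normalization (-0.012, limma adjusted p = 0.83). Among lists, camera with an estimated correlation lost the Nodal/activin list for activin A in WT (0.199) and the BMP list for BMP4 in WT (0.0692) and in the interaction (0.439). Fry gave 0.092 for the Nodal/activin list in WT, 0.0685 in the activin interaction and 0.177 for the BMP list in the BMP interaction, and turned the BMP list of KO8 around (0.143). Leaving out 1 library gave 0.00065 to 0.284 for the BMP list in the BMP interaction. It turned the BMP list around in the activin interaction (0.745 to 0.996) and in the mean of KO7 and KO8 (0.803 to 0.906).

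Of 2099 results of named genes under other settings 1925 stayed the same, 141 were weaker, 32 stronger and 1 reversed, and of 3156 with 1 library left out 2791 stayed the same. For lists 560 of 639 and 753 of 806 stayed the same. No scaling moved the median of all genes by more than 0.1.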

Other observations

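The genes of this part were chosen after their values were seen. Genes of chromosomes 6 and 8, which moved together over long stretches, were not set apart among them. Over 11736 genes tested in the count table, the untreated TPM table and the mean of the treated tables, 582 were called in all 3, and 363 of them went in the same direction each time, 148 higher and 215 lower. At 2-fold or more in each, 3 genes rose, namely Id2 (1.61, 2.02 and 1.66), a BMP target that holds back differentiation, and the homeobox genes Vax2 (1.10, 1.91 and 2.37) and Irx5 (1.31, 1.48 and 1.08). Genes that fell included, besides Hmces, Prr23a2 (-1.90, -1.57 and -1.61), the X-linked homeobox gene Rhox10 (-2.08, -1.56 and -1.48), the RNA export gene Nxt2 (-2.05, -1.42 and -1.36), Tarm1 (-1.56, -1.26 and -1.40), Kbtbd11 (-1.51, -1.12 and -1.86), Extl1 (-1.54, -1.32 and -1.12), Hal (-1.21, -1.55 and -1.02), which breaks down histidine, and Ppp2r2c (-1.19, -1.01 and -1.19). The highest adjusted p of these genes was that of Irx5, at 0.036 with edgeR in the count table and 0.034 with limma in the untreated TPM table.

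Further genes in the same direction in all 3 data sets were transcription factors of early lineages. Zic2 (1.45, 0.87 and 1.48), known from formative pluripotency, Sall3 (2.07, 0.92 and 0.92) and the Wnt target Sp5 (1.08, 1.23 and 0.85) rose, as did Klf6 (0.81, 1.11 and 0.95) and the small GTPase gene Rhob (0.82, 1.48 and 1.10). Gata6 (-1.81, -0.93 and -1.17), needed for primitive endoderm, and the caudal homeobox gene Cdx1 (-0.98, -0.78 and -1.43) fell.

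In WT cells Lefty1 stood at 33.5 reads per 1000000 reads under activin A, 159 under BMP4 and 100 under LDN193189, so activin A went with the lowest WT level of these 3 tables. In HMCES-KO Lefty1 stood at 122 in KO1 and 149 in KO2 under activin A, 74.8 and 173 under BMP4, and 28.1 and 79.8 under LDN193189, so the order of the tables differed between the lines. These comparisons between tables were not tested.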
